A study of Mus musculus with 10 samples.

How the data were processed

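H2A.X, a variant of histone H2A, was profiled by native chromatin immunoprecipitation and sequencing of mononucleosomes released with micrococcal nuclease, per the labels' protocols. The 10 libraries came from mouse cell lines at passage 15 to 20, 1 library per line. An embryonic stem cell (ESC) control line and an ESC test line were profiled beside 8 induced pluripotent stem cell (iPSC) lines. SNEL lines 1 and 3 were made with Sall4, Nanog, Esrrb and Lin28. OSKM lines 5, 8 and test were made with Oct4, Sox2, Klf4 and Myc, and OSK lines 4, 2 and 9 with Oct4, Sox2 and Klf4. The lines of a factor set were treated as its replicates, so p-values measure the spread between libraries of different lines. That spread can hold differences in library depth and processing as well as between lines. No line was measured more than once.

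CASAVA and Bowtie2 2.1.0 are named in the submitters' processing notes, with genome build mm9. The deposited file of the ESC control line held every aligned read with its position and its mapping quality score. The deposited file of each other line was a list of regions called against the ESC control line, with 1 list per line and no pooling. RSEG, a hidden Markov model caller of broad domains, is known only from the names of the deposited lists, and its version and settings are not given in the sources used here. Each region had a class and a score, and the authors' score is read here as the mean difference in read count per bin, line minus control, without scaling to depth. That reading came from the values and is not stated by the authors. The OSK lists had 7 columns and the other lists 6, the further column being a score whose meaning is not stated. Region borders fell on multiples of 1350 bp in 7 lists, 2150 bp in the ESC test list and 2900 bp in the OSKM test list. List format and bin size were thus tied to factor set and line, and a difference between OSK and the other sets cannot be told apart from a difference in how the lists were made.

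The class named for the first sample of a list is called line-enriched here and the class named for the second sample control-enriched. This assignment was inferred from the order of the names and from the control reads. The rank correlation over regions between score and control reads per bin was negative in 8 of the 9 lists, from -0.81 to -0.27 (Spearman; regions are not independent replicates). It was 0.36 in SNEL 3, where the orientation stayed unsettled. A further check asked whether regions with negative scores held at least that many control reads, and it passed in 94.0% to 99.8% of such regions. Regions with positive scores passed it nearly as often in SNEL 1 and more often in SNEL 3 and OSKM test, so it does not settle the orientation of those lists. Because scores are not scaled, a line-enriched region can hold fewer reads from the line than from the control, and both classes are relative to the rest of the same list.

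Counts of regions and covered length were computed per line and class, and compared between factor sets by 2-sided exact permutation tests over all splits of the lines, with the absolute difference of group means as statistic. The family held 16 tests, adjusted by the Benjamini-Hochberg method. Group-specific regions were merged regions touched by at least 1 bp in every line of one group and in no line of the other. Overlap of lists was the Jaccard index in bp for 36 pairs of lines per class, set beside 1000 seeded circular shifts within chromosomes, beside the overlap of independent lists of the same length, and beside 100 simulations. In the simulations each line differed from the control only in depth, reads per 100 kb bin were drawn from Poisson distributions around the distinct reads of the control line, and all lists shared 1 control draw. The mean index within factor sets minus that between them was tested with a 1-sided exact permutation over 560 labelings of the 8 iPSC lines. Region counts per chromosome were compared with chromosome length by binomial tests, called at more than 2 times the expected count and an adjusted p under 0.05. Regions of 1 line are not independent, so those p-values describe the lists only.

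The ratio of line to control reads was estimated in regions as score plus control reads per bin, divided by control reads per bin. It counted control reads with the same start and strand once and used regions of at least 10 bins with at least 70% of control reads at a mapping quality of 10 or more. Those filters were not applied to the ratios given for chromosome Y. Autosomes 1, 8 and 11 were left out of its reference. The estimate, its filters, the counting of distinct reads and the autosomes left out were all chosen after the data were seen, as were the comparison in 10 kb bins and the analysis of GC content. The choice of distinct reads followed a comparison of all, well-mapped and distinct reads against the scores. The read filter of the authors is not known, so ratios are estimates for listed regions only. GC content was taken from the sequences of the control reads.

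The control library held 28980424 aligned reads from 1 lane, of which 76.5% had a mapping quality of at least 10 and 83.1% were distinct in start and strand. The depth of the other libraries is unknown, and no counting interval is given for them. The main tests, the alternatives and the rule for named regions were fixed before the data were examined, and alternatives added later are identified as such. Named regions were the 3 longest group-specific regions per class and direction in the 3 comparisons of single factor sets, the 5 longest regions in all iPSC lines and not in the ESC test line, and the longest region of each line. Gene lists fixed in advance were not run, because no mm9 annotation was used here, and regions are named by mm9 coordinates, counted from 1. The scripts were tested on simulated lists for the comparison of group-specific regions, where they recovered 30 of 30 and 50 of 50 planted regions. The formula of the ratio gave 1.47 for a planted chromosome ratio of 1.5. That simulation used bins without called regions, classes or filters, so it did not test the estimated ratio as applied to the lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.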

Results

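H2A.X deposition was mapped in an ESC control line, an ESC test line and 8 iPSC lines, and the question was whether deposition relative to ES cells differed between lines made with different factor sets. The study design marks the SNEL lines as positive and the OSKM lines as negative for tetraploid complementation, the strictest test of pluripotency, and gives no status for the OSK lines. The control library held 28980424 reads. The other 9 libraries were represented by lists of regions that differed from the control line, 22984 regions in all, with a median length of 159.5 kb. Line-enriched regions are those called for the tested line and control-enriched regions those called for the control line. Each value below is for 1 library of 1 line.

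Lines of the same factor set differed widely. SNEL 1 had 1555 line-enriched regions over 1182 Mb and 1298 control-enriched regions over 499 Mb. SNEL 3 had 53 line-enriched regions over 0.579 Mb and 638 control-enriched regions over 2374 Mb, 89.4% of the genome. OSKM 5 and OSKM 8 resembled each other, with 1320 and 1227 Mb line-enriched and 245 and 252 Mb control-enriched. OSKM test had 258 Mb line-enriched and 296 Mb control-enriched, the latter in 3754 regions. OSK 4 and OSK 2 were line-enriched over 1873 and 1824 Mb and control-enriched over 7.41 and 27.4 Mb, whereas OSK 9 had 473 and 185 Mb. The ESC test line, included as the background between ES lines, was line-enriched over 450 Mb and control-enriched over 556 Mb. Its line-enriched length lay mostly on a few chromosomes, with 167.5 Mb on 1, 118.8 Mb on 8, 73.6 Mb on 11, 64.7 Mb on X and 13.0 Mb on Y. That value is therefore a poor measure of the usual difference between ES lines. Longest regions were on chromosome X from 35167501 to 50828850 in OSKM 5, OSKM 8, OSK 4, OSK 2 and OSK 9. They were on chromosome 8 from 24206851 to 40196400 in the ESC test line, on chromosome 1 from 24850801 to 33559650 in SNEL 1 and on chromosome 6 from 90526401 to 94363100 in OSKM test, all line-enriched. In SNEL 3 the longest region was control-enriched, on chromosome 14 from 59938651 to 106843050.

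**Figure D1:**
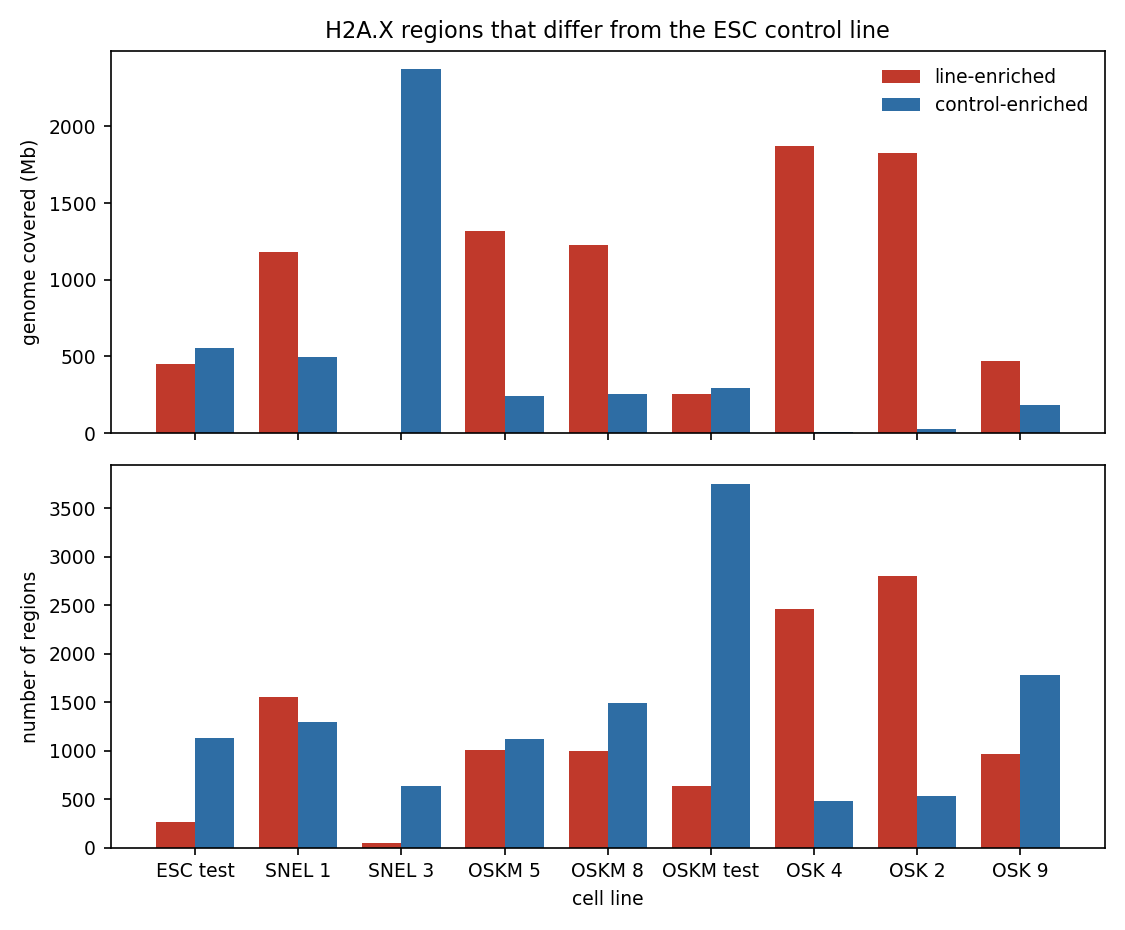
Genome covered in Mb (top) and number of regions (bottom) per cell line, with red bars for line-enriched and blue bars for control-enriched regions, 1 library per line. SNEL 3 was control-enriched over 2374 Mb, while OSK 4 and OSK 2 were line-enriched over 1873 and 1824 Mb.

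SNEL against OSKM was the comparison named by the study design. Control-enriched regions covered 1437 ± 1326 Mb (SD, n = 2) in SNEL and 264.6 ± 27.6 Mb (SD, n = 3) in OSKM lines, and both SNEL lines lay above all 3 OSKM lines. The exact permutation test gave p = 0.1 (2-sided, adjusted p = 0.4), the smallest p that 2 lines against 3 allow. This order rests on which class of the SNEL 3 list belongs to the control, which stayed unsettled: with the 2 classes of SNEL 3 exchanged, a setting chosen after seeing the data, SNEL 3 would be control-enriched over 0.579 Mb, below all OSKM lines, and the difference would be -14.6 Mb (exact permutation p = 1). The difference of 1172 Mb was 235 Mb without SNEL 3 and 2110 Mb without SNEL 1, and -251.8 Mb with regions whose absolute score was at least the median (exact permutation p = 0.1). That cutoff, 5.10, removes every control-enriched region of SNEL 3 with a positive score, since the highest was 3.98. It keeps every control-enriched region of OSKM 8, where none scored above -7.07. Scores are not scaled to depth, so that setting says little about the difference. The ESC test line, at 556 Mb, also lay above all OSKM lines. Line-enriched regions covered 591 ± 835 Mb (SD, n = 2) in SNEL and 935 ± 588 Mb (SD, n = 3) in OSKM lines (exact permutation p = 0.5). Without SNEL 3 that difference turned to 247 Mb higher in SNEL. The median score of control-enriched regions in SNEL 3 was 1.75, above 0, while it was negative in every other list.

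Regions found in both SNEL lines and in no OSKM line, or the opposite, were few. Both SNEL lines alone were line-enriched in 14 merged regions, which spanned 0.763 Mb. That span is not shared length, since each line need touch only 1 bp of a merged region. The longest were on chromosome X from 122673151 to 122852700 and from 121223251 to 121342050, and on chromosome 11 from 34333201 to 34445250. All OSKM lines and no SNEL line were line-enriched in 2 regions, on chromosome 8 from 90746801 to 93361950 and on chromosome 2 from 125829451 to 126342450. For control-enriched regions, 3 were specific to SNEL, on chromosome 5 from 128868301 to 129001950, on chromosome 12 from 19886851 to 19889550 and on chromosome 7 from 15712651 to 15714000. The opposite pattern held for 21, led by chromosome 12 from 116716301 to 116951200, chromosome 4 from 146776051 to 146989400 and chromosome 12 from 18220701 to 18427500. The control-enriched counts rested in part on SNEL 3, whose long control-enriched regions join those of other lines when merged. The line-enriched list of SNEL 3 held only 53 regions over 0.579 Mb, which limits what both SNEL lines can share. Every SNEL-specific line-enriched region touches that list. Of control reads in its 53 regions, 53.6% had a mapping quality of at least 10, against 76.5% of all control reads. Without SNEL 3 there were 238 line-enriched and 305 control-enriched group-specific regions, and without SNEL 1 there were 258 and 128. Without OSKM test the counts were 71 and 51, and without OSKM 5 they were 26 and 41. In 10 kb bins, which are not merged, 165.5 Mb was control-enriched in both SNEL lines and in no OSKM line, against 1.49 Mb in the opposite direction, while 0.18 Mb was line-enriched in SNEL alone, against 4.52 Mb in OSKM alone. These values also turned when the classes of SNEL 3 were exchanged, to 0.04 against 2.2 Mb control-enriched and 88.4 against 0.45 Mb line-enriched.

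OSK and OSKM lines differ in the use of Myc. OSK lines had lower control-enriched coverage, 73.1 ± 97.0 Mb (SD, n = 3) against 264.6 ± 27.6 Mb (SD, n = 3), with all 3 OSK lines below all 3 OSKM lines. The exact permutation p was 0.1 (2-sided, adjusted p = 0.4), the smallest that 3 lines against 3 allow. Line-enriched coverage was 1390 ± 795 Mb (SD, n = 3) in OSK and 935 ± 588 Mb (SD, n = 3) in OSKM lines (exact permutation p = 0.5). All OSK lines and no OSKM line were line-enriched in 232 merged regions, and no region showed the opposite. These merged regions spanned 135.5 Mb, which is not the length shared by all OSK lines. The longest were on chromosome 15 from 85297051 to 88456050, on chromosome 13 from 55856251 to 58257900 and on chromosome 5 from 119215801 to 121595850. All OSKM lines and no OSK line were control-enriched in 93 merged regions, which spanned 24.7 Mb. They were led by chromosome 8 from 121942801 to 123439950, chromosome 2 from 179203051 to 180222300 and chromosome 8 from 126758251 to 127510200. Only 8 control-enriched regions were specific to OSK, the longest on chromosome 3 from 142261651 to 142285950, on chromosome X from 4658851 to 4677750 and on chromosome 13 from 4558951 to 4572450. Without OSK 9 the counts for both directions together rose to 773 line-enriched and 329 control-enriched, and without OSKM test to 350 and 342. Without OSKM 5 the control-enriched count was 166. The line-enriched count fell to almost none when only regions whose absolute score was at least the median of all lists, 5.10, were kept. Median line-enriched scores were -4.72, -4.43 and -3.75 in OSK 4, OSK 2 and OSK 9, under that cutoff in absolute value. Scores are not scaled to depth, so the fall does not show that these regions are weak. Requiring a larger share of the merged region lowered both counts, as given with the other settings below. The OSK lists had another format than all other lists, so factor set and list format cannot be told apart.

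SNEL lines had higher control-enriched coverage than OSK lines, 1437 ± 1326 Mb (SD, n = 2) against 73.1 ± 97.0 Mb (SD, n = 3), with an exact permutation p of 0.1 (2-sided, adjusted p = 0.4), the smallest possible. With the classes of SNEL 3 exchanged, that line would lie below every OSK line, and the difference would be 176.9 Mb (exact permutation p = 0.7). With only regions whose absolute score was at least the median of all lists, the difference turned negative, with OSK lines higher. That cutoff keeps every OSK control-enriched region but no control-enriched region of SNEL 3 with a positive score. The turn therefore says little about the difference. All OSK lines and no SNEL line were line-enriched in 330 merged regions, which spanned 221.8 Mb. The longest, on chromosome Y from 2902501 to 15901650, held 0 control reads and a score near 0, and the next were on chromosome 2 from 168852601 to 174787200 and on chromosome 8 from 126542251 to 129787650. SNEL-specific line-enriched regions numbered 15, led by chromosome X from 121223251 to 121342050, chromosome 18 from 3002401 to 3076650 and chromosome 4 from 145108801 to 145176300. Control-enriched merged regions specific to SNEL numbered 18 and spanned 11.5 Mb. They were led by chromosome 2 from 54885601 to 58908600, chromosome 12 from 89523901 to 92677500 and chromosome 14 from 25535251 to 26694900. In 10 kb bins, which are not merged, 342 Mb was control-enriched in both SNEL lines and no OSK line, against 1.89 Mb in the opposite direction, and 0.26 Mb was line-enriched in SNEL alone, against 267 Mb in OSK alone, of which 29.6% was on chromosome X and 16.1% on chromosome 8. In OSK 9, line-enriched regions covered 83.8% of X and 89.1% of chromosome 8 but at most 13.9% of any other autosome. This limits where all OSK lines can share line-enriched bins. Exchanging the classes of SNEL 3 gave, in 10 kb bins, 0.01 against 3.08 Mb control-enriched and 79.4 against 39.0 Mb line-enriched. Control-enriched merged regions specific to OSK numbered 35, led by chromosome 12 from 116716951 to 116950500, chromosome 4 from 146776051 to 146988000 and chromosome 4 from 144936001 to 145083150. Without SNEL 3 the control-enriched count for both directions together rose from 53 to 658. Without SNEL 1 it was 262, and without OSK 9 it was 118. The line-enriched count rose from 345 to 759 without SNEL 1 and to 983 without OSK 9.

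Against OSKM and OSK lines together, SNEL lines had higher control-enriched coverage, with SNEL values of 499 and 2374 Mb and a range of 7.41 to 296 Mb over the 6 other iPSC lines. The exact permutation test gave p = 0.0357 (2-sided, n = 2 and 6), the smallest p this design allows, and the adjusted p over 16 tests was 0.4. The difference of means was 1268 Mb, 331 Mb without SNEL 3 and 2206 Mb without SNEL 1, each then with an exact permutation p of 0.143. With the classes of SNEL 3 exchanged, it would be 81.1 Mb (exact permutation p = 0.643), and SNEL 3 would lie below all 6 other lines. The ESC test line, at 556 Mb, lay above SNEL 1. When regions touching any ESC test region were left out, the difference fell to 4.25 Mb (exact permutation p = 0.857). Long regions are removed by size alone under that rule: of the 2374 Mb in SNEL 3, with a median region length of 1162 kb, 37.2 Mb stayed, so this setting says little about the difference. With regions whose absolute score was at least the median of all lists, the difference was -158 Mb (exact permutation p = 0.179). That cutoff removes every control-enriched region of SNEL 3 with a positive score, so it also says little about the difference. No difference in the number of regions was detected, with an exact permutation p of 0.429 for line-enriched and 0.571 for control-enriched regions.

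The highest overlaps were those of particular pairs of lines. OSK 4 and OSK 2 had a Jaccard index of 0.876 for line-enriched regions, and OSKM 5 and OSKM 8 one of 0.825. SNEL 1 overlapped OSKM 5 at 0.714 and OSKM 8 at 0.662, and SNEL 3 at 0.000258, where the length of the SNEL 3 list allows at most 0.00049. The index of SNEL 1 and SNEL 3 would be 0.479 if the classes of SNEL 3 were exchanged, where the lengths allow at most 0.498 and independent lists would give 0.423. OSKM test overlapped OSKM 5 at 0.0642 and OSKM 8 at 0.0572. For control-enriched regions, the index was 0.567 for OSKM 5 and OSKM 8, 0.469 for SNEL 1 and OSKM 5, and 0.437 for the ESC test line and SNEL 1. The mean index within factor sets exceeded that between them by 0.0603 for line-enriched regions (exact permutation p = 0.204, 1-sided, n = 8 lines) and by 0.0800 for control-enriched regions (exact permutation p = 0.0607, 1-sided, n = 8 lines). It depended on the measure: the share of regions touching gave an excess of 0.170 for line-enriched regions (exact permutation p = 0.0179), and a reciprocal overlap of 50% gave 0.122 for control-enriched regions (exact permutation p = 0.0107). The line-enriched difference was -0.0038 without OSK 4 and -0.0031 without OSK 2. The control-enriched difference was 0.120 without SNEL 1 (exact permutation p = 0.0429) and 0.141 without OSK 9 (exact permutation p = 0.0381). The ESC test line overlapped iPSC lists at a mean of 0.177 for line-enriched and 0.217 for control-enriched regions. All lists shared the control library. Circular shifts gave a lower overlap than observed for 21 of 36 line-enriched and 30 of 36 control-enriched pairs at an adjusted p under 0.05, where the smallest p the shifts allow was 0.001. For SNEL 1 and OSKM 5, line-enriched regions of independent lists would give an index of 0.307. On autosomes the observed index for that pair was 0.753, and simulated lines that differed from the control only in depth gave a mean of 0.435. Over the 28 pairs without SNEL 3, whose size fixes most of its simulated line-enriched indices at 0, 6 line-enriched and 7 control-enriched indices lay above all 100 simulations, and 22 and 19 lay below all of them. Examples of the latter were the ESC test line with OSK 9 (0.265 against a simulated mean of 0.495) and OSKM 5 with OSK 9 (0.0864 against 0.248). Part of the overlap above shifts may come from the shared control library, which could not be split.

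**Figure D2:**
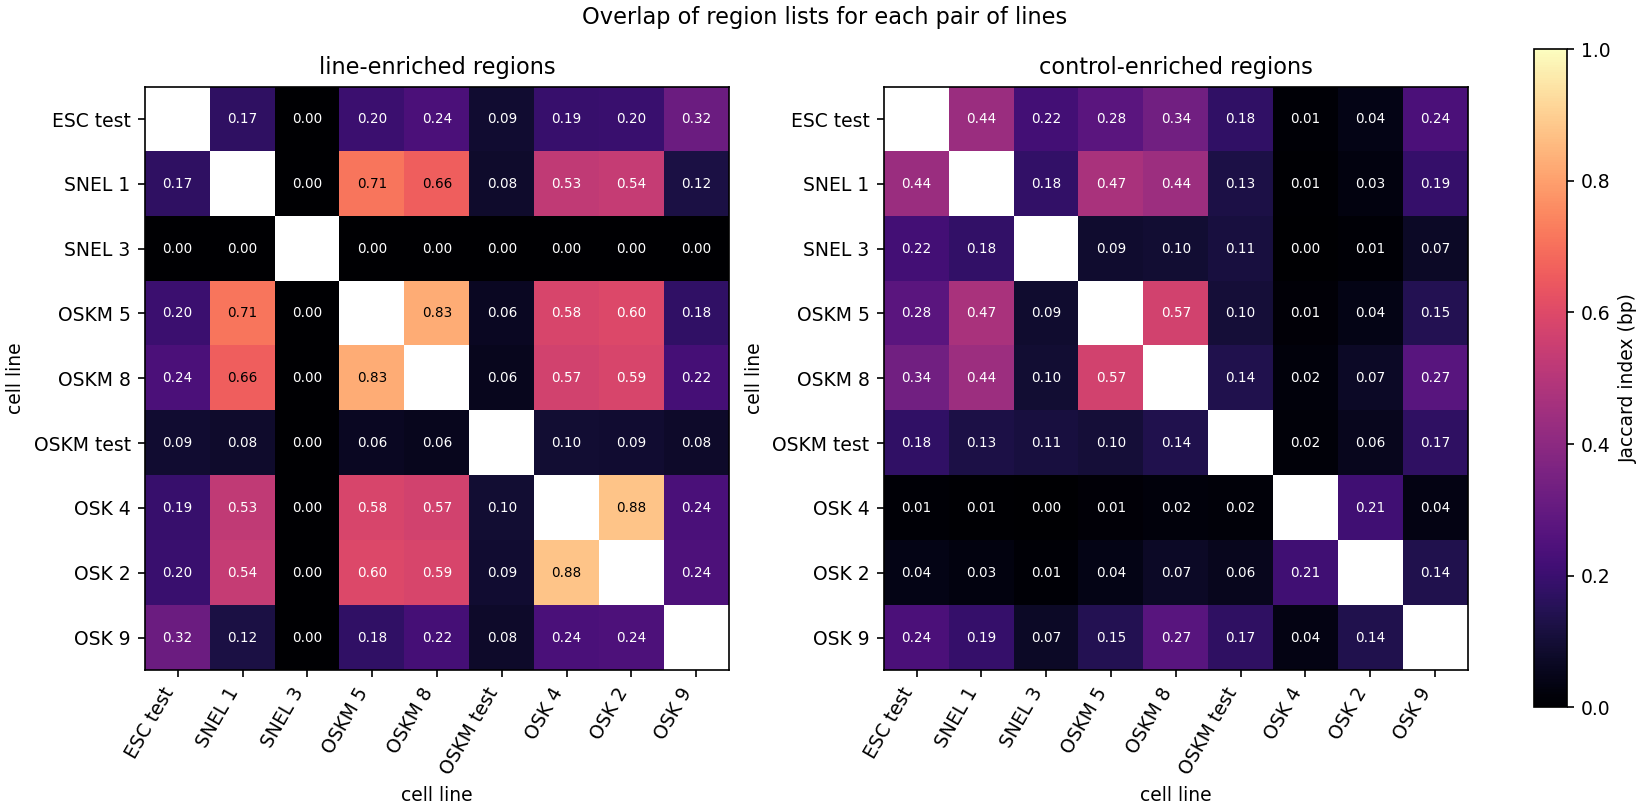
Jaccard index in bp for each pair of lists, for line-enriched (left) and control-enriched (right) regions, with 1 row and 1 column per cell line. OSK 4 with OSK 2 (0.876) and OSKM 5 with OSKM 8 (0.825) gave the highest line-enriched values, and SNEL 1 with SNEL 3 gave 0.000258.

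Whole chromosomes stood out in several lines. In the ESC test line, line-enriched regions covered 90.2% of chromosome 8, 84.9% of chromosome 1 and 60.4% of chromosome 11, against 0 to 3.21% of the other 16 autosomes. In OSK 9 they covered 89.1% of chromosome 8, against 2.76% to 12.7% of those 16 autosomes, and in OSKM 8 they covered 80.5%, against 24.2% to 55.2%. The proximal and distal parts of chromosome 8, of equal length, were covered at 86.8% and 93.6% in the ESC test line, 84.9% and 93.4% in OSK 9, and 83.4% and 77.7% in OSKM 8. In SNEL 3, control-enriched regions covered 30.5% of chromosome 8 and 82.3% to 96.6% of the other autosomes outside 1 and 11. The estimated ratio of line to control reads in line-enriched regions of chromosome 8 was 1.49 times that of listed regions on the other autosomes in OSKM 8, 1.51 times in OSK 9 and 1.68 times in the ESC test line. Against line-enriched regions alone it was 1.34 times in OSKM 8 and 1.22 times in OSK 9. In the ESC test line it was 1.13 times, over only 9.25 Mb of reference. By region counts, 4 of the line-enriched tests and 1 of the control-enriched tests passed the rule against chromosome length among all 378 tests. They were chromosomes 1, 8, 11 and X in the ESC test line at 3.13, 2.23, 3.99 and 3.28 times the expected count (adjusted binomial p of 2.01e-13, 0.00169, 1.17e-13 and 1.32e-12), and chromosome Y in OSK 4 at 4.54 times (adjusted binomial p of 0.000487).

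**Figure D3:**
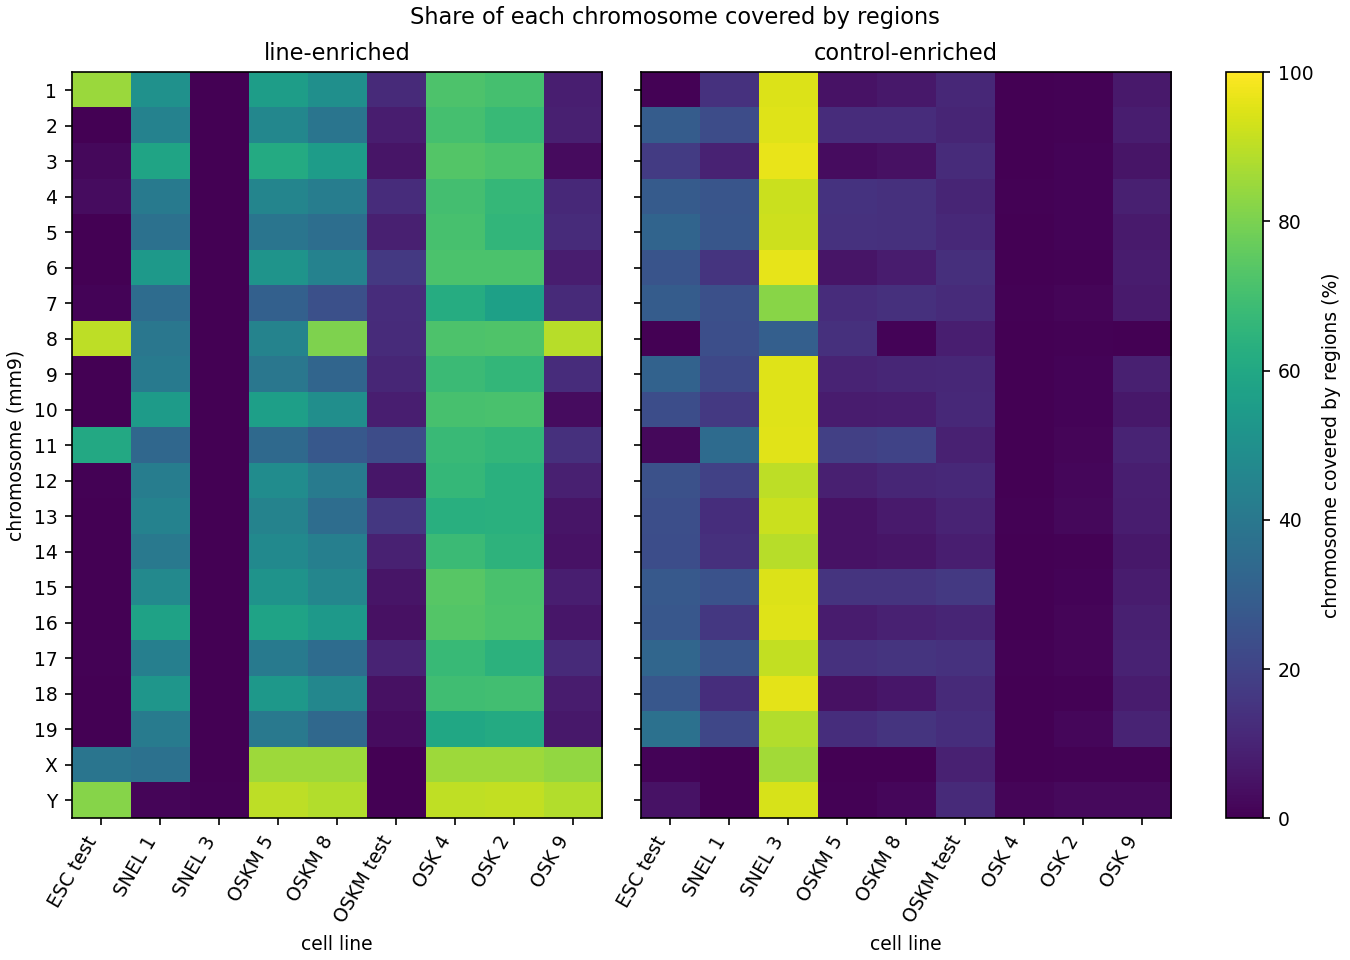
Share of each mm9 chromosome (rows) covered by line-enriched (left) and control-enriched (right) regions in each cell line (columns), in percent. Chromosome 8 stood out in the ESC test line (90.2%), OSKM 8 (80.5%) and OSK 9 (89.1%), and most of chromosome Y is a span without control reads.

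**Figure D4:**
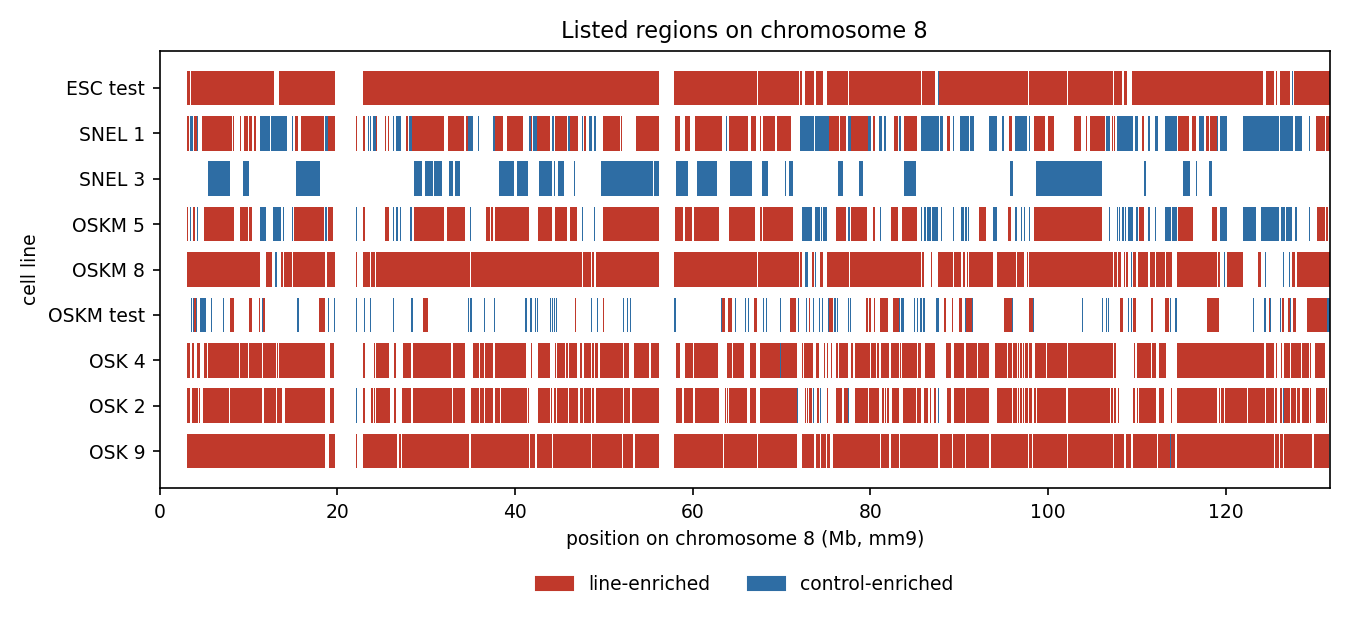
Line-enriched (red) and control-enriched (blue) regions along chromosome 8 (Mb, mm9) in the 9 lists, 1 row per cell line. Line-enriched regions covered 90.2% in the ESC test line, 80.5% in OSKM 8 and 89.1% in OSK 9, and SNEL 3 had control-enriched regions over 30.5%.

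Chromosome X was line-enriched over 83.8% to 85.5% of its length in OSKM 5, OSKM 8, OSK 4, OSK 2 and OSK 9, over 38.8% in the ESC test line, 37.4% in SNEL 1 and 0 in OSKM test. In SNEL 3 it was line-enriched over 0.0689% and control-enriched over 86.0%. The control line had 3.69 well-mapped reads per kb on X and 7.60 to 11.8 on the autosomes. In those 5 lines the estimated ratio on X was 0.933 to 1.095 times that of listed autosomal regions. The large Y region that 6 lists gave as line-enriched and SNEL 3 as control-enriched, about 13.0 Mb long, held 0 control reads.

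The control line's own reads described where the regions lay. Genome-wide, bins of 10 kb had a median of 9.5 control reads per kb. Line-enriched regions lay near that level in 8 of the 9 lists, at 0.823 to 1.14 times the median, and control-enriched regions lay at 1.11 to 1.63 times in 7 lists. The exceptions were the 53 short line-enriched regions of SNEL 3, at 18.7 times, and the control-enriched regions of OSK 4 and OSK 2, at 8.28 and 3.26 times. In OSK 4 only 28.2% of control reads in those regions had a mapping quality of at least 10. The share was 53.6% in the line-enriched regions of SNEL 3. Between factor sets the exact permutation p was 0.1 or higher in all 6 tests, and 0.1 is the smallest possible. GC content separated the classes in some lines. Control reads in line-enriched and control-enriched regions had a GC content of 39.8% and 46.7% in SNEL 1, 39.6% and 47.7% in OSKM 5, and 39.6% and 45.7% in OSKM 8. The ESC test line had 41.96% and 44.5%. The order was opposite in OSKM test (43.6% and 41.4%) and OSK 9 (44.2% and 42.03%), where the line-enriched 10 kb bin had the lower GC content in 38.2% and 46.3% of pairs of bins (40.2% and 25.2% without chromosomes 1, 8, 11, X and Y). In OSK 4 (42.04% and 38.3%) and OSK 2 (41.9% and 39.6%) the pooled values weigh read-rich control-enriched regions that are poorly mapped, and by bins the shares were 45.6% and 49.9%, so OSK 2 showed no order. The estimated ratio in line-enriched regions was 1.47 to 1.77 times that in control-enriched regions in the 8 lists with both, but the classes and this ratio come from the same read differences.

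**Figure D5:**
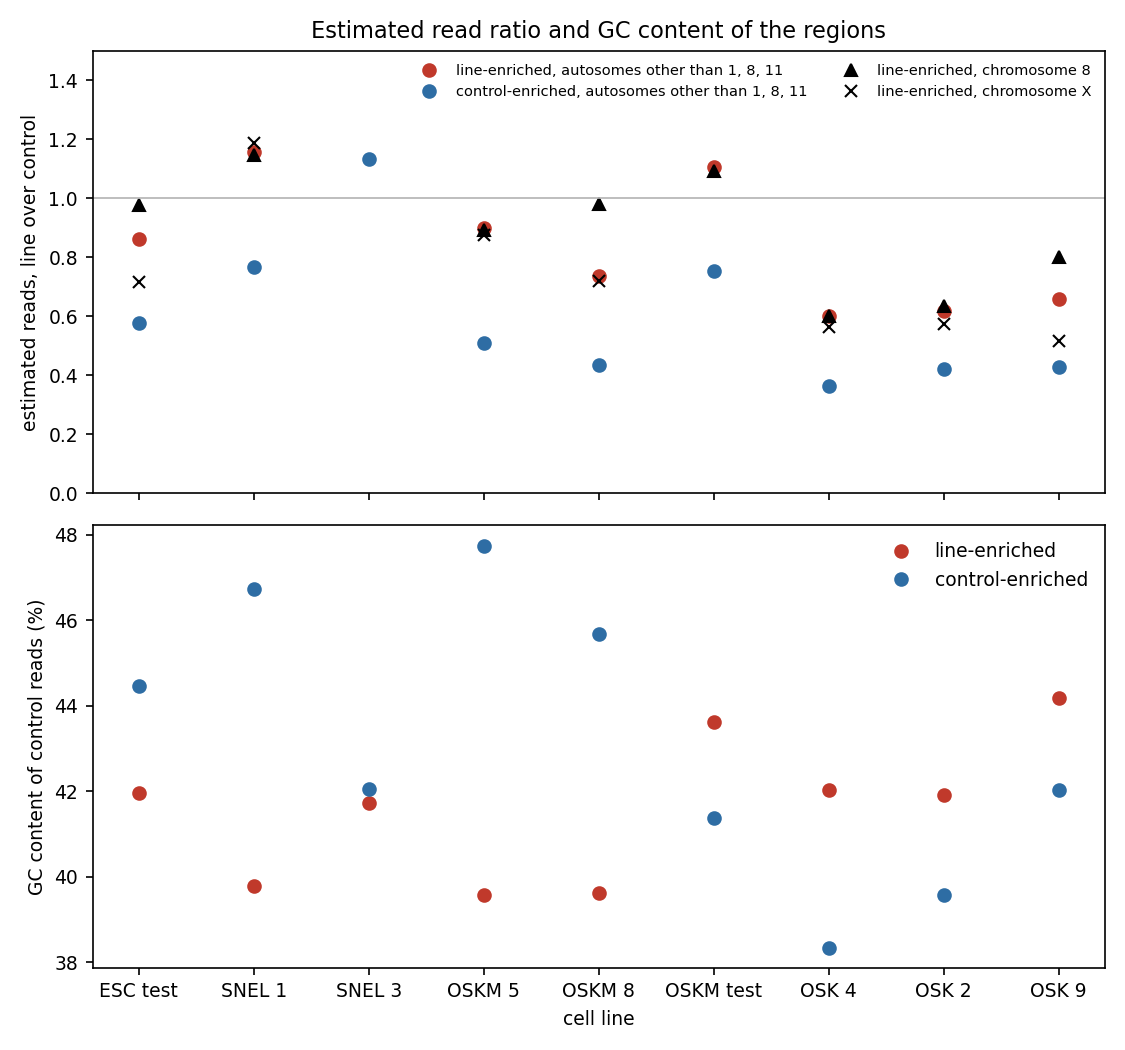
Estimated ratio of line to control reads (top, no unit) and GC content of control reads in percent (bottom) per cell line, for line-enriched (red) and control-enriched (blue) regions, with black triangles for chromosome 8 and crosses for X. Chromosome 8 lay above the red points in OSKM 8 and OSK 9, and GC content was lower in line-enriched regions of SNEL 1, OSKM 5 and OSKM 8. The vertical axis of the GC panel does not start at 0.

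Across all 8 iPSC lines, 1 line-enriched merged region was present in every line and not in the ESC test line, on chromosome 12 from 74467351 to 76661500. Control-enriched merged regions of that kind numbered 11, of which the 5 longest were on chromosome 1, from 24737001 to 44528400, 109025501 to 128664450, 47016451 to 62805300, 158098501 to 172994400 and 128687401 to 141779700. The ESC test line was control-enriched over only 0.395% of chromosome 1 and line-enriched over 84.9%. SNEL 3 was control-enriched over 94.7% of it, so long regions of this kind can arise there without a locus common to iPSC lines. Merged regions need not share bases between lines. In 10 kb bins, 0 Mb was line-enriched in all 8 iPSC lines, and 0.6 Mb was control-enriched in all of them, of which 0.03 Mb was not control-enriched in the ESC test line. SNEL 3 was line-enriched over only 0.579 Mb, which limits what all lines can share. Exchanging its classes gave 13.7 Mb line-enriched and 0.1 Mb control-enriched in all 8 lines, and 94 line-enriched and 0 control-enriched merged regions that were not in the ESC test line.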

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

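The comparison of SNEL with the other iPSC lines was fixed in advance, the test against other splits was read only after its result was seen, and the look at control reads in single bins was not planned.

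The 2 groups of iPSC lines differed in control-enriched coverage, with both SNEL lines above all 6 OSKM and OSK lines (exact permutation p = 0.0357, adjusted p = 0.4). The orientation of the SNEL 3 list is unsettled, and with its classes exchanged SNEL 3 would lie below all 6 lines, at 0.579 Mb (exact permutation p = 0.643 for the groups). The merged regions that separate SNEL from these 6 lines were few, 13 line-enriched and 15 control-enriched. For control-enriched regions this is in part because the long SNEL 3 regions join those of other lines when merged. In 10 kb bins, 147 Mb was control-enriched in both SNEL lines and none of the 6, against 0.98 Mb in the opposite direction. Line-enriched bins stayed few, 0.18 against 1.2 Mb, where SNEL 3 was line-enriched over only 0.579 Mb. The same exchange turned these into 0 against 0.94 Mb and 24.4 against 0.43 Mb. Of the 28 splits of the 8 lines into 2 and 6, 6 gave as many line-enriched regions and 4 as many control-enriched ones, the real split included, so chance was not excluded. The highest other counts were 471, for OSK 4 and OSK 2 against the rest, and 92, for SNEL 3 and OSKM test against the rest, several times the real counts. By merged regions alone, other splits gave higher counts than SNEL against the rest. Such counts can follow list length, since OSK 4 and OSK 2 had the most line-enriched coverage, 1873 and 1824 Mb. No other grouping of the lines was tested.

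A pile of control reads that no comparison used by itself stood out: 1 bin of 10 kb, on chromosome 2 from 98500001 to 98510000, held 7.07% of all control reads, 2048845 reads at 4145 distinct starts and strands. Only 26.9% of these had a mapping quality of at least 10, against 76.5% of all control reads. The bins with the next most reads lay on chromosome 9 from 3000001 to 3040000, with 1.04% to 3.94%. Most of these reads could not be placed with confidence, so no H2A.X signal is read from them.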

How the results depend on the processing

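The alternatives were fixed before the data were examined, with 3 exceptions chosen after seeing the data. They were the restriction to lists with the shortest bin, which leaves out OSKM test, the exchange of the classes of SNEL 3, and the estimated ratio with all control reads. The rule for leaving out over-represented chromosomes was fixed in advance, and it gave 1, 8, 11, X and Y. Of 222 values under other settings, 157 kept their direction and their side of an unadjusted p of 0.05 or stayed within 1.5 times, 44 moved by more, 17 changed direction, 2 became weaker and 2 stronger. Of 192 values with 1 line left out, 154 stayed, 25 moved, 9 changed direction, 2 became weaker and 2 stronger. In tests of 2 or 3 lines against 3 the smallest p is 0.1, so no value could cross 0.05 and only direction was assessed. A difference could there change in size and still count as kept. For SNEL minus OSKM, control-enriched, 1172 Mb became 235 Mb without SNEL 3. These totals therefore overstate how stable the values were. Gene lists were not run. The estimated ratio was checked with all control reads in place of distinct ones, and line-enriched over control-enriched ratios were then 1.43 to 1.72. The depth of 9 libraries is unknown, so weak regions cannot be told from missed ones. No paired analysis was possible because the groups compared share no line numbers. The cause of the changes listed here was not tested, except that fewer lines or a stricter rule for shared regions change a count by construction.

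With scores at or above the median, the difference in region number was 28.7 for SNEL minus OSKM, line-enriched (exact permutation p = 0.3), and -858.5 for SNEL minus OSK, control-enriched (p = 0.3). The difference in control-enriched coverage was -251.8 Mb for SNEL minus OSKM (exact permutation p = 0.1), -64.9 Mb for SNEL minus OSK (p = 0.6) and -158 Mb for SNEL minus both (p = 0.179). These signs can follow from the cutoff itself, since scores are not scaled to depth. It removes every control-enriched region of SNEL 3 with a positive score and no control-enriched region of the OSK lines. With regions at or above the median length, control-enriched counts were higher in SNEL, by 131.7 than OSKM (exact permutation p = 0.2) and by 307 than both (p = 0.107). Without regions touching the ESC test list, control-enriched coverage differed by -19.1 Mb for SNEL minus OSKM (exact permutation p = 1) and by 4.25 Mb for SNEL minus both (p = 0.857), but that rule removes long regions by size and left 37.2 of 2374 Mb in SNEL 3 and 34.3 of 499 Mb in SNEL 1.

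With the classes of SNEL 3 exchanged, the difference in region number was 216 for SNEL minus OSKM, line-enriched (exact permutation p = 0.8), and -255.5 for SNEL minus OSK, control-enriched (p = 0.7). Line-enriched coverage differed by 843 Mb for SNEL minus OSKM (exact permutation p = 0.5), 388 Mb for SNEL minus OSK (p = 0.7) and 616 Mb for SNEL minus both (p = 0.429). Control-enriched coverage differed by -14.6 Mb for SNEL minus OSKM (exact permutation p = 1) and 81.1 Mb for SNEL minus both (p = 0.643). Group-specific regions numbered 45 line-enriched for SNEL and OSKM, and 54 line-enriched and 108 control-enriched for SNEL and OSK. The excess of overlap within factor sets was -0.00103 for line-enriched regions (exact permutation p = 0.482). The density of control reads in control-enriched regions, in multiples of the genome median, was then 8.51 higher in SNEL than in OSKM (exact permutation p = 0.4) and 5.56 higher than in OSK (p = 0.7). Of the SNEL comparisons of covered length, only the control-enriched differences from OSK and from both kept their direction, and they fell from 1364 to 176.9 Mb and from 1268 to 81.1 Mb.

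Group-specific regions, line-enriched then control-enriched, changed as follows. Requiring 50% of the merged region gave 8 and 46 for SNEL and OSKM, 124 and 49 for OSK and OSKM, 210 and 89 for SNEL and OSK, and 7 and 36 for SNEL and both. Scores at or above the median gave 480 control-enriched for SNEL and OSKM, 1 line-enriched for OSK and OSKM, 18 and 222 for SNEL and OSK, and 89 control-enriched for SNEL and both. Because scores are not scaled to depth, that cutoff removes regions unevenly between lists and classes. Lists with the shortest bin gave 71 and 51, 350 and 342, and, for SNEL and both, 42 and 23. Without chromosomes 1, 8, 11, X and Y, line-enriched counts were 7 for SNEL and OSKM and 6 for SNEL and both.

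The excess of overlap within factor sets was 0.170 for line-enriched regions as the share of regions touching (exact permutation p = 0.0179), with p from 0.0179 to 0.482 over its alternatives other than leaving out a line. It was 0.122 for control-enriched regions with a reciprocal overlap of 50% (exact permutation p = 0.0107), with p from 0.0107 to 0.175. Chromosomes past the rule numbered 13 line-enriched and 5 control-enriched against control reads, and 13 and 7 by covered length.

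Leaving out 1 line at a time gave these lowest and highest values. The difference in region number ranged from -827 to 675 for SNEL minus OSKM, line-enriched, from -293 to 463.5 for SNEL minus OSK, control-enriched, and from -1427 to 75.3 for SNEL minus both, line-enriched. Coverage differed by -934 to 247 Mb for SNEL minus OSKM and by -1162 to 19.3 Mb for SNEL minus both, line-enriched, and by 331 to 2206 Mb for SNEL minus both, control-enriched. Other coverage differences kept their sign but not their size: 235 to 2110 Mb for SNEL minus OSKM and 426 to 2301 Mb for SNEL minus OSK, control-enriched, -1389 to -208 Mb for SNEL minus OSK and 116 to 913 Mb for OSK minus OSKM, line-enriched, and -247 to -159 Mb for OSK minus OSKM, control-enriched. The differences in region number left also kept their sign: -1656 to -340.5 for SNEL minus OSKM, -1693 to -377.5 for OSK minus OSKM and -889 to -114 for SNEL minus both, control-enriched, and 838 to 1753 for OSK minus OSKM and -2026 to -524 for SNEL minus OSK, line-enriched. Group-specific counts were 21 to 258 and 29 to 305 for SNEL and OSKM, 239 to 773 and 111 to 342 for OSK and OSKM, 359 to 983 and 58 to 658 for SNEL and OSK, and 13 to 158 and 15 to 230 for SNEL and both. Without SNEL 3 the line-enriched differences between SNEL and OSKM, and between SNEL and both, changed sign. The excess of overlap within factor sets ranged from -0.0038 to 0.184 for line-enriched and from 0.0353 to 0.141 for control-enriched regions.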

Other observations

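The tests here were chosen after the patterns were seen, except the GC content of chromosome 8 and the simulated overlap.

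Chromosome Y differed between lines. Over the part with control reads, control-enriched regions of the ESC test line covered 795.5 kb and held an estimated 0.197 reads per control read, against 0.590 in its control-enriched autosomal regions, all control reads counted. In OSKM test, 1899.5 kb was control-enriched, at 0.537 against 0.761. The Y values were taken over all such regions, whereas the autosomal values used only regions past the filters on length and mapping quality. The Y and autosomal values are therefore not like for like. Counted with distinct control reads the ratios were -0.29 against 0.577, and 0.299 against 0.754, and a value below 0 shows that the read filter of the lists was not matched there. In SNEL 3, control-enriched regions left out 59.6% of the proximal and 79.4% of the distal part of chromosome 8, of equal length, against 7.34% of the autosomes other than 1, 8 and 11.

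The estimated ratio over listed autosomal regions was 1.02 in SNEL 1, 1.13 in SNEL 3, 0.816 in OSKM 5, 0.658 in OSKM 8, 0.924 in OSKM test, 0.60 in OSK 4, 0.614 in OSK 2 and 0.532 in OSK 9. It pools both classes, whose shares differ between lists, so it is at best a rough proxy for relative depth. SNEL lines lay above the 6 other iPSC lines in this pooled ratio (exact permutation p = 0.0357, 2-sided, n = 2 and 6, the smallest possible). With the score of SNEL 3 read in the opposite direction, which stayed open, its ratio would be 0.867, below OSKM test (exact permutation p = 0.0714). In the ESC test line the pooled ratio was 0.58, from 534 Mb of control-enriched and 9.25 Mb of line-enriched regions. The 0.60 of OSK 4 came from 0.926 Mb of control-enriched and 1384 Mb of line-enriched regions. Those values thus do not imply a similar depth.

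Chromosome 8 was line-enriched over most of its length in the ESC test line, OSKM 8 and OSK 9, and extra copies of chromosome 8 are known in cultured mouse pluripotent cells. A shortage of control reads was argued against, since the control line had 8.43 well-mapped reads per kb there and 7.60 to 11.8 on other autosomes, and base composition likewise, at a GC content of 43.3% against 39.3% to 44.4%. An extra copy in part or all of those cultures may account for it: the lowest coverage of either part was 77.7%, above every other autosome outside 1 and 11 in the same line. The estimated ratios, 1.49 to 1.68 times other listed regions but 1.13 to 1.34 times line-enriched ones, leave the number of copies and the share of cells open. The ESC test line is no reprogrammed line, so the factor set is not needed for the pattern, and karyotypes would test it.

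Chromosome X was line-enriched over most of its length in OSKM 5, OSKM 8 and all OSK lines. More copies of X were argued against, since the highest estimated ratio on X was 1.095 times that of autosomal regions. The median was 0.973, consistent with read differences that were not scaled to depth on a chromosome with few control reads, where a shallower line loses fewer reads per bin. Whether H2A.X itself differed on X was not tested.

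By the classes as named, SNEL 1 overlapped OSKM 5 and OSKM 8 more than SNEL 3. A depth gap with a shared control library stayed open: each observed Jaccard index exceeded all its simulations, of which the highest was 0.445, but that bound, set in advance, decides nothing, since the simulations overshot the observed index in 22 line-enriched and 19 control-enriched pairs of the 28 without SNEL 3 and so did not describe the lists. Base composition may account for it: line-enriched 10 kb bins had the lower GC content in at least 93.1% of pairs of bins, and in 75.4% in the ESC test line (92.5% without chromosomes 1, 8, 11, X and Y). GC bias of the libraries and chromatin that follows GC content stay open. The factor set cannot be told apart, since only 0.0218% of the genome was line-enriched in SNEL 3, and for control-enriched regions the index with SNEL 3 was 0.183 (permutation by circular shifts, p = 0.391), against 0.469 and 0.441 with OSKM 5 and OSKM 8, where the lengths of the 2 lists allow at most 0.210, and with the classes of SNEL 3 exchanged the line-enriched index would be 0.479 of at most 0.498.

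For regions in every line of one group and none of the other, OSK and OSKM lines gave 232 line-enriched and 101 control-enriched regions. The 10 splits of these 6 lines are too few for a share under 0.05. For line-enriched regions 1 split, the real one, gave as many, and the highest other count was 79. For control-enriched regions 2 splits did, and the highest other count was 131, for OSK 4, OSK 2 and OSKM test against the rest.

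The comparisons of SNEL with single factor sets also have only 10 splits each, too few for a share under 0.05. SNEL and OSKM lines gave 16 line-enriched and 24 control-enriched group-specific regions, with as many in 7 and 5 splits, the real one included. The highest other counts were 467 and 137, both for SNEL 3 and OSKM test against the rest, several times the real counts. SNEL 3 and OSKM test had the least line-enriched coverage of these lines, 0.579 and 258 Mb. The line-enriched count can thus follow list length, and no other structure of the lines was tested. SNEL and OSK lines gave 345 and 53, with as many in 3 and 2 splits, and the highest other counts were 610 and 59, both for OSK 4 and OSK 2 against the rest.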
